A study of Mus musculus with 8 samples.

How the data were processed

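RNA sequencing measured transcript levels in pools of about 50 mouse embryos each, in 3 libraries of inner cell mass (ICM) from blastocysts at embryonic day 3.5, 3 libraries of ICM from diapaused blastocysts and 2 libraries of epiblast from post-implantation embryos at day 6.5. Per the labels' protocols, the embryos came from C57BL/6 females, diapause was induced on day 3.5 with tamoxifen and 0.5 mg of Depo Provera, and diapaused blastocysts were collected 5 days later. The labels' protocols also state that the trophectoderm of blastocysts was lysed by antibody and complement, and that RNA was amplified with a kit for very small inputs before library preparation. They describe the libraries as biological triplicates and duplicates.

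The deposited values are a signal per gene that the authors' column names call adjusted TPM (TPM is a transcript abundance scaled to a common total), and how they were adjusted is not given in the sources used here. The columns did not share a total, their sums ranging from 720674 in ICM replicate 2 to 1179026 in diapaused ICM replicate 1, so the values were handled as a signal and not as TPM proper, the unit that had been assumed when the tests were fixed. The plan called for another test only if the values were counts or already on a log scale. The planned test on log2(value + 1) was therefore kept. Bowtie 0.12.5, DESeq (version not given) and the mouse build mm9 are named in the submitters' processing notes, without their roles. The quantification program, the annotation, any filter on reads and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been shared in ways that cannot be checked. Read totals are not part of the deposited values, the sequencing depth is therefore unknown, and no counting interval is given. Genes at 1 or more numbered 14634 to 15130 per library, and exact zeros numbered 0 to 5 per library among 38924 genes.

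All computations started from these values. Genes with a value of at least 1 in at least 2 libraries were kept, which left 17698 of 38924. The scale was log2(value + 1), on which a fold change understates the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted the 8 libraries together with a mean per group and no other term, so that the 3 groups shared an estimate of the spread (residual degrees of freedom 5, prior degrees of freedom 3.97, prior variance with a trend on mean level). The 3 pairs of groups were each tested with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 17698 genes and a threshold of 0.05. Standard errors are those of the moderated fit. A group mean is the mean of the adjusted TPM over its libraries, given with its SD. Data for diapaused ICM against ICM were simulated in 5 runs with 17698 genes, 200 of them changed. The changed genes were drawn only from genes with an ICM level of about 5 or more, so recovery at lower levels was not assessed. They were also far fewer than the 2360 genes called in the data, so the shares recovered may differ there. The test recovered 12.8% of genes changed by 1 on the log2 scale and 89.8% of those changed by 2, with 5.35% of calls false. With nothing changed it called at most 1 gene in a run, and 0 lists in the only run where lists were tested. The simulated genes varied independently of each other, so that 0 cannot speak for lists whose genes are correlated.

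Gene lists numbering 43, with 1060 members of which 1055 were in the file and 896 were tested, were written before the data were examined. They cover mTORC1 and AMPK components, nutrient transport and metabolism, translation, the cell cycle, pluripotency, chromatin, signalling and stress pathways, and markers of other cell types. Members were matched by symbol, and where a symbol occurred on several lines (204 repeats) the line of highest mean was used. The 41 lists with at least 5 tested members were compared with all other genes by camera, from limma, with a preset correlation of 0.01 between genes. Camera with the correlation estimated from the data, and fry, were run as alternatives. With an estimated correlation, camera also refers its statistic to the few residual degrees of freedom, which makes it stricter by itself. Fry tests whether a list moves in a direction on balance and does not compare it with other genes. Counts of members past the threshold are given from the adjustment over all genes and adjusted over the list alone.

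The genes named were chosen by a rule also fixed before the data were examined. In each comparison it took the 6 highest and 6 lowest fold changes among genes past the threshold whose groups did not overlap and whose mean was at least 10 in the higher group. Symbols of predicted genes and small RNAs were left out. It added up to 3 members with the smallest adjusted p of lists marked beforehand, up to 2 of the other lists, and a fixed set of genes of the mTOR, AMPK, amino acid, lipid and pluripotency machinery. For genes apart in diapaused ICM from both other groups it took 6 in each direction. List members named outside this rule were chosen after their values were seen and serve only to say which members a small count holds. Some items covered by the rule are not reported here.

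The alternatives tried, all fixed beforehand except 1, were pseudocounts of 0.1 and 5, no filter on low values, a filter at 5, median-of-ratios scaling, quantile normalization, rescaling without abundant genes (the mitochondrially encoded genes, the cytosolic ribosomal protein genes and the 50 genes of highest mean), the replicate number as a block, only the groups compared in the fit, no trend, array weights, a minimum fold of 1.5, and each library left out in turn. Protein-coding genes alone were tested as the alternative chosen after seeing the data, with gene types from GENCODE M21, to which 37607 gene identifiers matched (21226 of them protein-coding). GENCODE M21 is built on another assembly than mm9, so it served only for gene types and transcript sequences and no coordinates are given. Transcripts near-identical to those of other genes were found with BLAST 2.17.0 at 95% identity over at least 50% of the transcript. Figures were drawn with matplotlib 3.10.9.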

Results

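Transcript levels were measured in 3 libraries of inner cell mass (ICM), 3 of diapaused ICM and 2 of post-implantation epiblast, each from a pool of about 50 mouse embryos. The ICM is the inner part of the blastocyst, which gives rise to epiblast and primitive endoderm, and diapause is a reversible arrest of the blastocyst before implantation. Levels are adjusted TPM, given as mean ± SD with n = 3 for ICM, n = 3 for diapaused ICM and n = 2 for epiblast. Fold changes are on the scale log2(value + 1), which understates changes of genes with low values, and are given ± SE. The read depth is unknown, since the values keep no counts. Genes at 1 or more numbered 14634 to 15130 per library.

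The 3 groups were well separated. The first principal component, with 46.6% of the variance, set the epiblast libraries (scores 100.4 and 114.5) apart from ICM (-32.06 to -25.23) and diapaused ICM (-45.28 to -41.75). The second, with 25.1%, separated ICM (53.19 to 58.52) from diapaused ICM (-57.38 to -42.94). Pearson correlations across genes were 0.944 to 0.968 within groups, 0.886 to 0.919 between ICM and diapaused ICM, and 0.818 to 0.864 between either and epiblast; genes are not independent replicates. Single abundant genes took unequal shares. Npm1, a nucleolar chaperone, held 9.71% and 8.41% of the summed values in the epiblast libraries and 0.979% to 3.21% in the others, and mitochondrially encoded genes held 2.01% and 2.03% in epiblast, 8.45% to 11.7% in ICM and 5.68% to 7.91% in diapaused ICM. Whether reads of Npm1 were shared with Gm14681 and Gm5611, picked after their values were seen and at 60990 ± 30620 and 16110 ± 9013 in epiblast, could not be checked, which leaves the share of Npm1 uncertain.

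**Figure D1:**
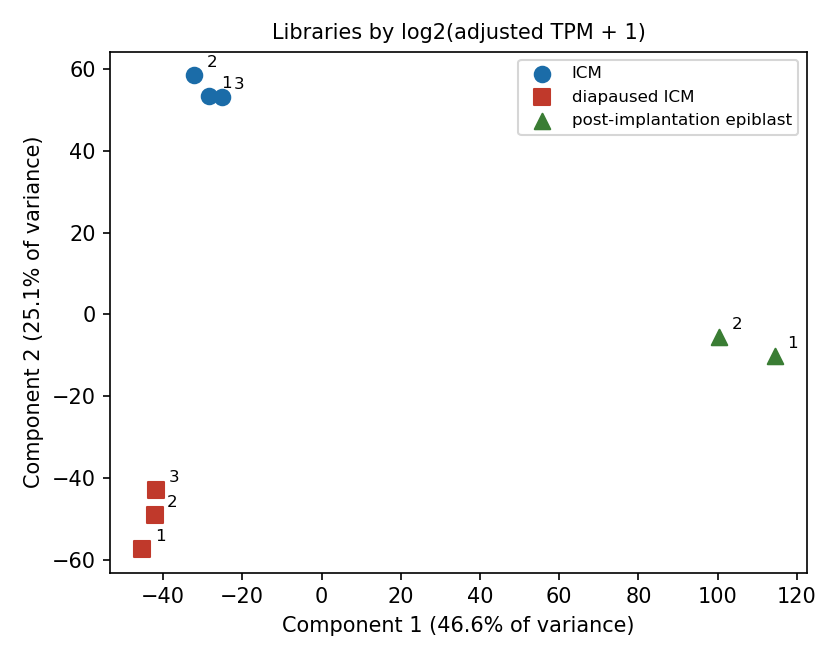
Scores of the 8 libraries on the first and second principal components of log2(adjusted TPM + 1), with the share of variance on each axis and the replicate number beside each symbol. Epiblast libraries lie at 100.4 and 114.5 on the first component, and ICM and diapaused ICM lie on opposite sides of 0 on the second.

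The comparison of diapaused ICM with ICM addresses which transcripts, above all of nutrient use and of the mTOR pathway, differ in the arrested embryo. The glutamine transporter gene Slc38a1 (ENSMUSG00000023169) was at 0.349 ± 0.0992 in ICM and 25.3 ± 5.68 in diapaused ICM (log2 fold change 4.27 ± 0.21, adjusted p = 1.5e-05), and its relative Slc38a2 (ENSMUSG00000022462) rose from 3.87 ± 0.476 to 81 ± 27.8 (4.03 ± 0.26, adjusted p = 4.0e-05). Prkaa2 (ENSMUSG00000028518), which encodes a catalytic subunit of the energy sensor AMPK, rose from 0.405 ± 0.311 to 6.12 ± 0.679 (2.36 ± 0.23). Fbp2 (ENSMUSG00000021456), for a gluconeogenic phosphatase, fell from 511 ± 210 to 2.95 ± 1.87 (-7.05 ± 0.45), the lowest fold change among the genes chosen for size. Next to it stood genes with oocyte or cleavage-stage expression: Pramel4 (-5.64 ± 0.26), Khdc3 (-5.22 ± 0.30), Crxos1 (-5.20 ± 0.67), Pramel5 (-4.71 ± 0.21) and Trim43a (-4.59 ± 0.21). The highest fold changes were those of the immediate-early gene Egr2 (ENSMUSG00000037868), from 0.129 ± 0.0875 to 55.4 ± 5.24 (5.64 ± 0.18), the tetraspanin gene Cd81 (5.54 ± 0.24), S100a1 (5.42 ± 0.43), Phldb2 (5.10 ± 0.64), Fxyd6 (5.00 ± 0.24) and B2m (4.91 ± 0.27).

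**Figure D2:**
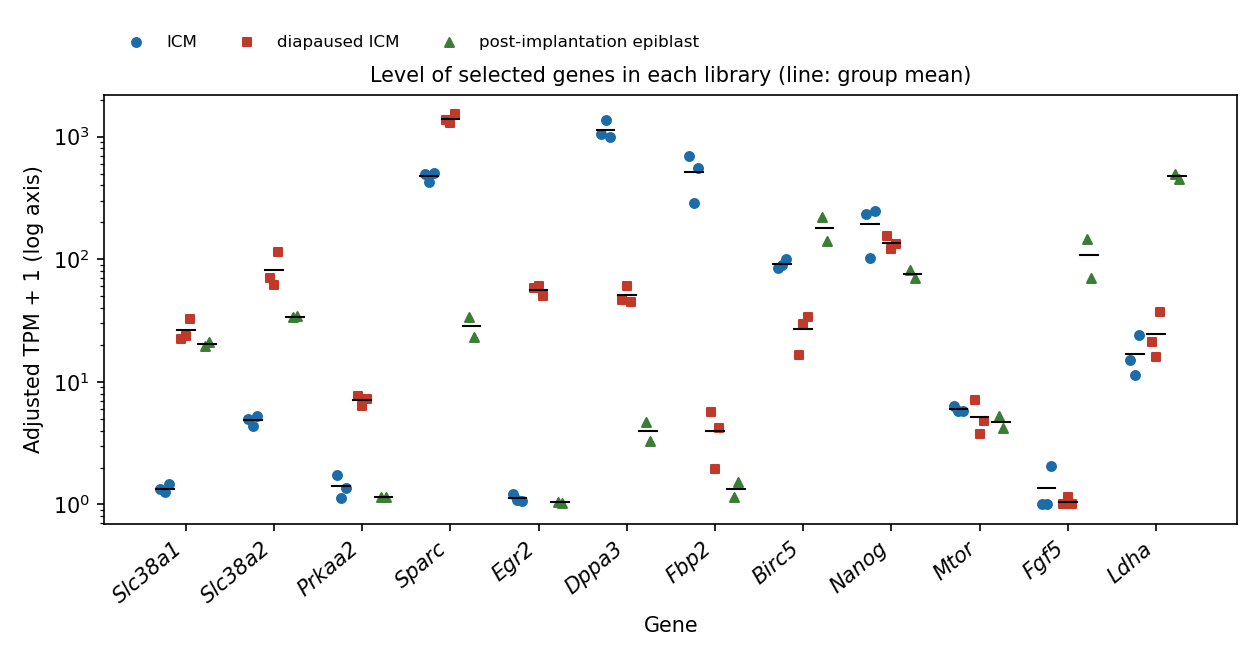
Adjusted TPM + 1 of 12 genes in each library, on a log axis, with 1 symbol per library and a line at the group mean. Slc38a1, Slc38a2, Prkaa2, Sparc and Egr2 lie higher in every diapaused ICM library than in every ICM library and Dppa3, Fbp2 and Birc5 lie lower, while Mtor and Nanog overlap between those groups.

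Mtor, which encodes the kinase of mTORC1, was at 5.02 ± 0.333 in ICM and 4.22 ± 1.71 in diapaused ICM (-0.26 ± 0.26, adjusted p = 0.58). Of 26 genes of mTORC1 and its activators, 1 rose and 1 fell (1 and 1 adjusted over the list alone): Rragd, for a Rag GTPase, went from 3.33 ± 1.77 to 19.8 ± 5.76, and Sec13 from 19.4 ± 2.41 to 8.85 ± 1.51. Of 19 genes of mTORC1 inhibition, 2 rose and 1 fell (2 and 3 adjusted over the list alone). Sesn2, a stress-induced inhibitor, rose (1.33 ± 0.20), while the calls of Eif4ebp2 (1.36 ± 0.38) and Deptor (-1.02 ± 0.24) were each lost without any of several libraries, for example at adjusted p = 0.11 without diapaused ICM replicate 1 for Eif4ebp2 and 0.079 without ICM replicate 1 for Deptor. Of 11 LKB1 and AMPK genes 3 rose and 1 fell. Beside Prkaa2, these were Prkab2 (1.27 ± 0.26; adjusted p = 0.056 without ICM replicate 1), Prkag2 (1.69 ± 0.36; 0.053 without diapaused ICM replicate 1) and, picked after its values were seen, Prkag1, which fell from 13.3 ± 2.27 to 6.65 ± 0.237. Stk11, which encodes LKB1, was at 28.2 ± 2.48 and 27.5 ± 3.20 (-0.04 ± 0.21), and Prkaa1 at 4.24 ± 1.78 and 5.6 ± 2.12. The AMPK list had a median fold change of -0.04, a mean of 0.34 and a median of 0.02 after quantile normalization, and like both mTORC1 lists it was not called as a list.

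Of 18 amino acid transporter genes 5 rose and 0 fell (6 and 0 adjusted over the list alone): Slc38a1, Slc38a2, Slc7a2 (2.01 ± 0.19) and, picked after their values were seen, Slc1a4 and Slc7a1. The list median was 0.60 (camera adjusted p = 0.00667, 0.408 with an estimated correlation). Of 24 cholesterol synthesis genes 13 rose and 0 fell (15 and 0 adjusted over the list alone). The median was 1.22 (2.51e-09, 0.0725 with an estimated correlation). Fdft1 rose from 5.77 ± 1.83 to 54.2 ± 4.84, Cyp51 from 3.37 ± 0.493 to 29.4 ± 5.97. Of 22 glycolysis genes 7 rose and 0 fell (10 and 2 adjusted over the list alone), among them the glucose transporter gene Slc2a3, from 24 ± 1.75 to 165 ± 33.6, and Ldhb (3.41 ± 0.37). That list had a median of 0.60 (0.00776, 0.589 with an estimated correlation, and 0.0776 without diapaused ICM replicate 3). Asns, for asparagine synthetase, rose from 39.5 ± 8.34 to 161 ± 18.2, and Oat and Mthfd1l rose too (2.31 ± 0.31 and 2.18 ± 0.26).

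Genes of lipid and mitochondrial oxidation went both ways or fell. Of 25 genes of fatty acid beta-oxidation 2 rose and 5 fell (3 and 5 adjusted over the list alone), with a median of 0.07 and a mean of -0.16. Camera did not call the list, while fry called it downward (adjusted p = 0.0399). After rescaling without abundant genes 0 rose and 5 fell. Acaa2 fell from 44.6 ± 10.2 to 6.96 ± 1.98, Acadvl from 24.9 ± 4.52 to 5.14 ± 0.839 and Etfb from 232 ± 37.7 to 68.1 ± 4.35. Cpt1a, for the carnitine transferase of fatty acid import, rose from 12.3 ± 0.801 to 22 ± 3.43 (0.78 ± 0.19, adjusted p = 0.030), a call lost in 7 of 8 fits without 1 library (0.054 to 0.091), after that rescaling (0.085), with the replicate number as a block or only the groups compared (0.056 each) and with a minimum fold of 1.5 (0.96). The lipid droplet gene Plin2 fell from 119 ± 14.3 to 24.4 ± 8.42, while Pnpla2, for a triglyceride lipase, was at 4.71 ± 3.84 and 5.77 ± 2.11 (adjusted p = 0.63). Of 68 nuclear genes of the respiratory chain 1 rose and 5 fell (1 and 5 adjusted over the list alone). The median was -0.32 (camera adjusted p = 0.00184, 0.45 with an estimated correlation). It was -0.48 after rescaling without abundant genes, with 1 rising and 10 falling, and fry did not call the list (0.0631). Cox7a2l rose (1.62 ± 0.21), and those that fell were Ndufs8 (-1.56 ± 0.21) and, picked after their values were seen, Uqcr10, Ndufs5, Ndufv2 and Cox8a. The 13 mitochondrially encoded genes had a median of -0.47 (0.0424, 0.748 with an estimated correlation), a call lost without ICM replicate 1 (0.26), ICM replicate 3 (0.195), diapaused ICM replicate 2 (0.0992) or diapaused ICM replicate 3 (0.303). After quantile normalization the median was -0.78, with 3 genes past the threshold, all lower, in place of 1. Of 23 TCA cycle genes 1 rose and 4 fell, without a call of the list, and Sucla2 fell from 108 ± 24.4 to 28.1 ± 6.60.

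Of 81 cytosolic ribosomal protein genes 25 rose and 1 fell (41 and 1 adjusted over the list alone). The median was 0.73 (camera adjusted p = 1.13e-12, 0.412 with an estimated correlation). Rps4x rose from 770 ± 59.0 to 2080 ± 215 and Rps27 from 102 ± 3.29 to 252 ± 41.1, and the gene that fell, picked after its values were seen, was Rps27l. That median was 0.49 after quantile normalization, with 15 rising and 2 falling. Of 47 ribosome biogenesis genes 0 rose and 6 fell (0 and 7 adjusted over the list alone). The median was -0.23 (0.00586, 0.408 with an estimated correlation). The RNA polymerase I gene Polr1b fell from 22 ± 4.28 to 7.07 ± 1.14. Of 41 translation factor genes 3 rose and 2 fell, a balance that turned to 1 and 5 after quantile normalization and to 0 and 8 after rescaling without abundant genes. The list median was -0.25, and -0.41 after that rescaling. Of 35 genes of G2 phase and mitosis 0 rose and 12 fell (0 and 24 adjusted over the list alone). The median was -0.91 (3.55e-10, 0.323 with an estimated correlation). Birc5 fell from 90.3 ± 7.73 to 25.8 ± 9.04, Bub1b from 71.3 ± 16.2 to 20.7 ± 7.28 and Plk1 from 35.1 ± 7.07 to 12.9 ± 2.97. Of 40 genes of DNA replication 0 rose and 7 fell (0 and 9 adjusted over the list alone), such as Rrm2 (-1.64 ± 0.21) and Gins1 (-1.46 ± 0.27), with a median of -0.42 (3.24e-04, 0.408 with an estimated correlation). After rescaling without abundant genes 11 fell, with a median of -0.58. The antiproliferative gene Btg2 rose (2.04 ± 0.29), while Myc was at 9.89 ± 2.90 and 20.1 ± 8.73 (adjusted p = 0.16) and Mycn at 3.43 ± 1.62 and 5.11 ± 0.615 (adjusted p = 0.52).

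Pluripotency genes did not move as a block. Nanog was at 193 ± 78.6 in ICM and 136 ± 18.1 in diapaused ICM (adjusted p = 0.49), Pou5f1 at 129 ± 9.76 and 106 ± 7.84 (0.38) and Sox2 at 1.74 ± 0.716 and 2.10 ± 1.30 (0.88). The values of Sox2 lay close to the filter of 1, so its missing call says little. Of 24 naive pluripotency genes 3 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of 0.02, a mean of -0.11 and a median of -0.13 after rescaling without abundant genes. Dppa3 (ENSMUSG00000046323) fell from 1130 ± 200 to 49.9 ± 8.45 (-4.48 ± 0.24), while Nr0b1 (2.15 ± 0.25) and Dnmt3l (1.41 ± 0.19) rose. Of 14 core pluripotency genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.0316, 0.545 with an estimated correlation), a call lost without ICM replicate 3 (0.118) or diapaused ICM replicate 2 (0.0703). Dppa2 fell from 81.3 ± 8.70 to 9.22 ± 1.01 and Dppa4 from 42.8 ± 14.3 to 6.49 ± 1.98, with Utf1, Trim28 and Tdgf1, and Lin28a was among those that rose, these 4 being picked after their values were seen. The DNA methylation cofactor gene Uhrf1 fell from 187 ± 25.2 to 33 ± 5.6 and Uhrf2 rose from 6.97 ± 0.686 to 34.3 ± 9.65. Kat8, which encodes the H4K16 acetyltransferase MOF, was at 2.41 ± 1.67 and 2.26 ± 1.43 (adjusted p = 1).

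Of 22 primitive endoderm markers 14 rose and 1 fell (15 and 1 adjusted over the list alone). The median was 1.2 (camera adjusted p = 2.51e-09, 0.324 with an estimated correlation). Srgn rose from 1.31 ± 0.684 to 26.3 ± 10.7, Dab2 from 12.2 ± 2.73 to 115 ± 62.1 and Lama1 from 16.2 ± 5.51 to 61.3 ± 3.84, and the member that fell was Gata6. Of 12 visceral endoderm markers 4 rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.65 (0.0141, 0.45 with an estimated correlation). They were Rhox5, from 26.3 ± 4.52 to 558 ± 8.32, Dkk1, from 3.40 ± 1.10 to 10.5 ± 0.680, Slc39a8 and Lefty1, with Hnf4a falling. Gata6, Slc39a8, Lefty1 and Hnf4a were picked after their values were seen. Of 17 trophectoderm markers 1 rose (Gata3, from 1.46 ± 0.949 to 8.41 ± 3.28) and 1 fell (Gm2a, -0.91 ± 0.22; 0.093 without ICM replicate 1). Of 21 blood and immune cell markers only 3 were tested, too few for a list test, and 2 rose. Both were uneven between pools, Laptm5 at 31.8 ± 18.5 and Cd68 at 45.2 ± 30.8 in diapaused ICM against 0.966 ± 0.197 and 6.29 ± 2.72 in ICM.

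The lists of hypoxia response, p53 targets and apoptosis, LIF signalling, FGF signalling and Wnt pathway components were not called. Of 18 genes of ATF4 and the unfolded protein response 8 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 2.07e-04, 0.412 with an estimated correlation), among them Atf3 (2.48 ± 0.27), Asns and Sesn2. Of 14 genes that respond to dissociation or heat 7 rose and 2 fell (11 and 2 adjusted over the list alone). The median was 1.17 (2.07e-04, 0.323 with an estimated correlation). Egr1 rose from 9.76 ± 9 to 159 ± 22.9. Picked after their values were seen were Fos and Jun, which also rose, and the 2 that fell, the heat shock genes Hspa8 and Hsph1. Immediate-early genes were not tested as a list of their own. Of 11 Wnt targets 3 rose and 0 fell (4 and 0 adjusted over the list alone): Dkk1, Fzd7 (2.03 ± 0.36) and Nkd1 (1.41 ± 0.34; 0.076 without ICM replicate 1), with a list median of 0.85 (0.00475, 0.323 with an estimated correlation). Of 17 imprinted genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 0.91 (0.0011, 0.324 with an estimated correlation). Peg3 rose from 2.44 ± 1.10 to 48.6 ± 7.22 and Impact from 1.46 ± 0.440 to 8.87 ± 0.753, and Snrpn fell from 24.8 ± 5.97 to 3.44 ± 1.30. Autophagy and lysosome genes were divided, 8 of 46 rising and 6 falling (9 and 6 adjusted over the list alone), and the paralogs Gabarapl1 and Gabarapl2 went opposite ways, from 6.81 ± 0.677 to 42.6 ± 2.20 and from 225 ± 13.5 to 18.2 ± 1.26.

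**Figure D3:**
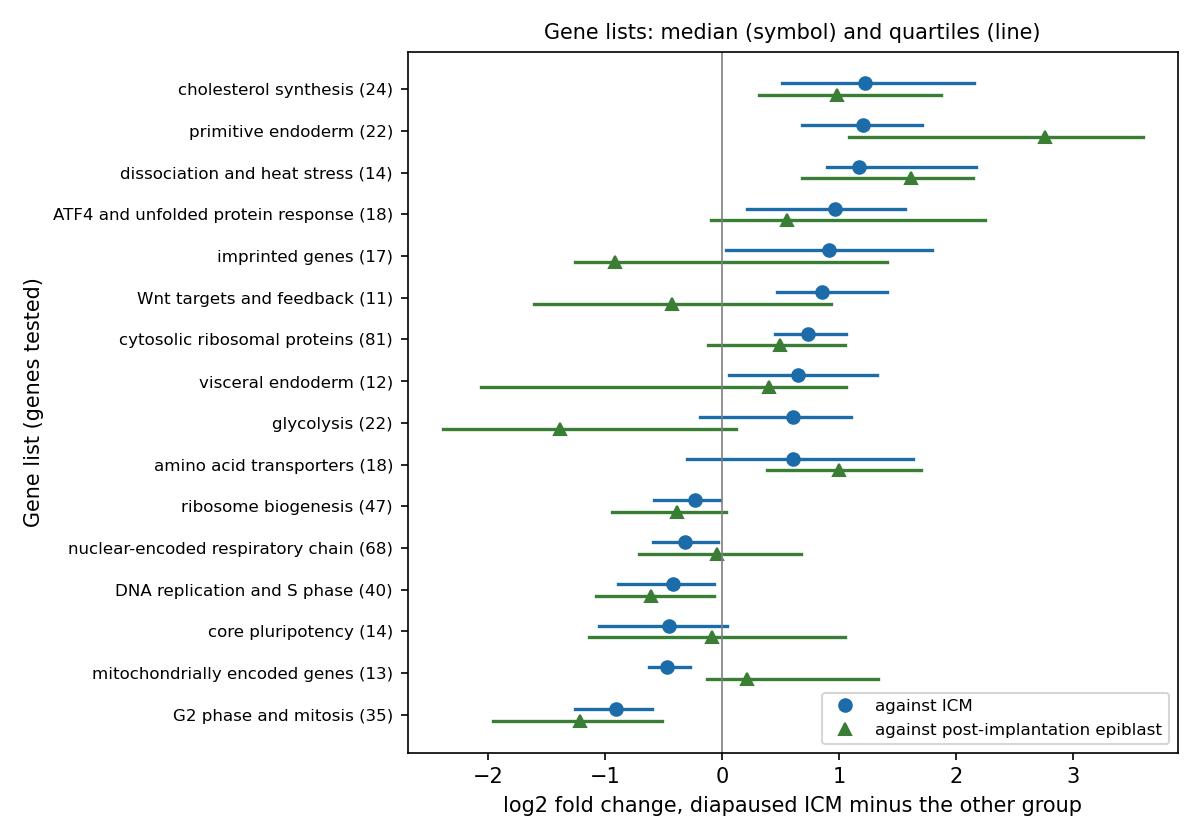
Median log2 fold change (symbol) and quartiles (line) of the 16 gene lists called between diapaused ICM and ICM (0 with an estimated correlation), for diapaused ICM against ICM (circles) and against post-implantation epiblast (triangles), with the number of genes tested. Cholesterol synthesis and primitive endoderm lie above 0 and G2 phase and mitosis below 0 in both comparisons, whereas glycolysis lies at 0.60 against ICM and -1.39 against epiblast; after median-of-ratios scaling the triangles of the nuclear-encoded respiratory chain and core pluripotency move to the other side of 0, at 0.10 and 0.04.

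By limma's moderated test, 1331 of 17698 genes were higher and 1029 lower in diapaused ICM than in ICM, 2360 in all, with 1106 and 811 of them changed by at least 2-fold. The groups did not overlap in 5442 genes (30.7%, where chance gives 10%), which included 2358 of those called. Rescaling without abundant genes shifted the median fold change of all genes by -0.139 and turned the split to 1068 higher and 1330 lower. It also turned without ICM replicate 2, to 1035 and 1113, and without ICM replicate 1 the count fell to 1404. Camera called 16 of 41 lists, 10 upward and 6 downward, with 0 left when the correlation was estimated. That setting also uses fewer degrees of freedom, so a lost call does not by itself show correlated genes. The Wnt targets had an estimated correlation of 0.01, equal to the preset, and their camera adjusted p still went from 0.00475 to 0.323. Diapaused embryos were also collected 5 days later than the ICM stage, and alone received the hormone treatment, so the arrested state, embryo age and treatment could not be separated. Differences in cell content, and in how complete the lysis of the trophectoderm was, could not be separated from these.

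The comparison of post-implantation epiblast with ICM addresses how transcripts differ between the blastocyst and the stage after implantation. The ICM gives rise to primitive endoderm as well as epiblast, and lysis of the trophectoderm is stated for blastocysts only. Differences in cell content and isolation could therefore not be separated from change within epiblast cells. The naive markers Dppa3 (1130 ± 200 in ICM, 3 ± 0.972 in epiblast; -8.16 ± 0.27, adjusted p = 2.5e-06), Fbxo15 (277 ± 25.6 and 1.45 ± 0.144) and Spp1 (179 ± 3.19 and 1.00 ± 0.313) fell, as did Fbp2 (-8.50 ± 0.50), Crxos1 (-6.72 ± 0.75) and Mras (-6.44 ± 0.31). Fgf5 (ENSMUSG00000029337), the growth factor gene of primed epiblast, rose from 0.359 ± 0.618 to 107 ± 53.5 (6.30 ± 0.40, adjusted p = 2.1e-05). Otx2 rose from 1.62 ± 0.967 to 59 ± 8.41 and Dnmt3b from 26 ± 6.18 to 253 ± 134. The other genes with the highest fold changes were Bex4 (6.85 ± 0.37), Bex1 (6.69 ± 0.26), Mns1 (6.31 ± 0.47), Ldhb (6.10 ± 0.41) and Cldn6 (5.69 ± 0.41). The primitive streak gene Mixl1 rose from 0.212 ± 0.104 to 12.8 ± 2.10 and T from 0.0285 ± 0.0291 to 1.85 ± 0.472. Pou5f1 fell from 129 ± 9.76 to 68.3 ± 3.02 and Nanog from 193 ± 78.6 to 74.8 ± 7.84, both calls being lost without epiblast replicate 1 (adjusted p = 0.080 and 0.12) or epiblast replicate 2 (0.089 and 0.16), and that of Nanog also without ICM replicate 1 (0.096) or ICM replicate 3 (0.094). Sox2, again close to the filter on low values, was at 1.74 ± 0.716 and 2.84 ± 2.61 (adjusted p = 0.64).

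Of 24 naive pluripotency genes 0 rose and 23 fell (1 and 23 adjusted over the list alone), with a median of -3.28 (camera adjusted p = 3.34e-19, 0.0853 with an estimated correlation), and of 24 primed epiblast genes 17 rose and 0 fell (19 and 1 adjusted over the list alone). The primed median was 2.80 (1.91e-08, 0.206 with an estimated correlation). Core pluripotency genes were divided, 4 of 14 rising and 6 falling, with Lin28b from 0.875 ± 0.473 to 44.8 ± 2.75 and Dppa2 from 81.3 ± 8.70 to 0.821 ± 0.0347. Of 12 genes of LIF signalling 0 rose and 6 fell (0 and 6 adjusted over the list alone), led by Stat3, from 67.6 ± 9.97 to 5.79 ± 0.405, with a list median of -1.01 (0.00293, 0.206 with an estimated correlation). Of 22 primitive endoderm markers 13 fell, such as Pdgfra from 27.8 ± 4.46 to 0.118 ± 0.00454, and 2 rose (13 and 3 adjusted over the list alone), Fst and Cited1, picked after their values were seen. That list had a median of -1.63 (2.24e-05, 0.453 with an estimated correlation). Of 12 visceral endoderm genes 5 rose and 2 fell. Camera did not call that list (adjusted p = 0.248), while fry called it upward (adjusted p = 0.00465). Spink3 and Apoa1 rose unevenly in the epiblast pools, to 31.2 ± 29.5 and 13.5 ± 6.44. The demethylase gene Tet2 fell from 54.2 ± 9.55 to 0.610 ± 0.0523.

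Of 22 glycolysis genes 13 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.37 (camera adjusted p = 1.21e-07, 0.316 with an estimated correlation), and Ldha rose from 15.8 ± 6.42 to 472 ± 37.1. Of 25 genes of fatty acid beta-oxidation 2 rose and 12 fell (2 and 13 adjusted over the list alone). The median was -0.94 (0.00166, 0.135 with an estimated correlation). Cpt1a fell from 12.3 ± 0.801 to 0.563 ± 0.0137 and Acaa2 from 44.6 ± 10.2 to 2.76 ± 0.0928, and the members that rose, picked after their values were seen, were Acsl4 and Acsl5. Plin2 fell from 119 ± 14.3 to 3.88 ± 0.183. Of 23 TCA cycle genes 2 rose and 7 fell (2 and 12 adjusted over the list alone), with a median of -0.78 (0.00677, 0.311 with an estimated correlation). The counts were 1 and 12 after median-of-ratios scaling and 0 and 12 after rescaling without abundant genes. Of 13 mitochondrially encoded genes 5 fell, mt-Co1 from 6850 ± 987 to 1850 ± 61.8, mt-Cytb (-2.44 ± 0.44) and, picked after their values were seen, mt-Co3, mt-Nd4l and mt-Nd1 (list median -1.02; 0.00388, 0.665 with an estimated correlation). After quantile normalization 8 fell, with a median of -1.39. Of 46 autophagy and lysosome genes 3 rose and 28 fell (4 and 30 adjusted over the list alone). The median was -1.55 (3.89e-09, 0.112 with an estimated correlation). Glb1 fell from 21.4 ± 3.37 to 0.546 ± 0.110, and those that rose, picked after their values were seen, were Gabarapl1, Ctsz and Tfe3. Of 11 LKB1 and AMPK genes 0 rose and 4 fell (0 and 5 adjusted over the list alone), Ulk1 (-2.68 ± 0.26), Prkag1 (-2.05 ± 0.22) and, picked after their values were seen, Prkab1 and Cab39, with a list median of -0.51 (0.00139, 0.252 with an estimated correlation). Slc38a1 rose to 19.3 ± 1.19 and Slc38a2 to 32.9 ± 0.388, in a transporter list with 4 rising and 5 falling. Of 17 imprinted genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 1.36 (0.00912, 0.374 with an estimated correlation), as in Grb10, from 1.51 ± 0.558 to 37.9 ± 2.40.

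By limma's moderated test, 2963 genes were higher and 2361 lower in epiblast than in ICM, 5324 in all. The groups did not overlap in 10434 genes (59%, where chance gives 20%). The split turned to 2219 higher and 2654 lower after median-of-ratios scaling and to 2004 and 2684 after rescaling without abundant genes, which shifted the median of all genes by -0.119 and -0.16. Without epiblast replicate 1 the count fell to 1788 (760 and 1028), and without epiblast replicate 2 to 2618. Camera called 11 of 41 lists, 3 upward and 8 downward, and 0 with an estimated correlation; with a filter of 5 in 2 libraries the TCA cycle (0.0622), LIF and JAK-STAT3 signalling (0.0542) and imprinted genes (0.0542) were no longer called.

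The comparison of diapaused ICM with post-implantation epiblast sets the arrested embryo against the stage that follows implantation. Cell content, isolation, the hormone treatment and the stage could not be separated here either. The highest fold changes in diapaused ICM were those of Egr1 (159 ± 22.9 against 0.891 ± 0.714 in epiblast; 6.45 ± 0.56, adjusted p = 1.1e-04), Mras (6.40 ± 0.31), the transcription factor gene Runx1 (93.7 ± 7.63 against 0.384 ± 0.0817; 6.10 ± 0.26) and Egr2 (5.75 ± 0.20). AY036118 (5.83 ± 0.56) and the pseudogene Fabp3-ps1 (5.74 ± 0.31) stood beside them, with reads that other copies may share. The lowest were those of Fgf5 (-6.59 ± 0.40), Otx2 (0.189 ± 0.219 against 59 ± 8.41; -5.67 ± 0.35), Cldn6 (-5.62 ± 0.41), Stxbp6 (-5.31 ± 0.34), Cald1 (-5.29 ± 0.38) and Tspan7 (-5.24 ± 0.25). Dnmt3b was at 9.81 ± 3.25 against 253 ± 134. Of 24 naive pluripotency genes 23 were higher in diapaused ICM and 0 lower (23 and 0 adjusted over the list alone), with a median of 3.10 (camera adjusted p = 1.07e-18, 0.0597 with an estimated correlation), as in Tfcp2l1, at 61 ± 7.27 against 0.732 ± 0.0350. Of 24 primed epiblast genes 19 were lower and 1, Lefty2, higher (20 and 1 adjusted over the list alone), with a median of -2.66 (5.34e-09, 0.156 with an estimated correlation); Lefty2 was picked after its values were seen. Nanog was at 136 ± 18.1 and 74.8 ± 7.84 (adjusted p = 0.11).

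Slc38a1 was at 25.3 ± 5.68 in diapaused ICM and 19.3 ± 1.19 in epiblast (0.35 ± 0.24, adjusted p = 0.27). Slc38a2 was higher in diapaused ICM (1.22 ± 0.29, adjusted p = 0.012), a call lost without epiblast replicate 1 (0.076) or epiblast replicate 2 (0.065). Of 18 amino acid transporters 8 were higher and 2 lower (8 and 2 adjusted over the list alone), among them Slc7a2 (12.6 ± 1.57 against 0.340 ± 0.123) and Slc7a1 (17.3 ± 5.25 against 1.40 ± 0.319), with Slc7a3 and Slc7a7, picked after their values were seen, lower. The list median was 1.00 (camera adjusted p = 0.00542, 0.297 with an estimated correlation, 0.0653 with a filter of 5 in 2 libraries). Of 11 LKB1 and AMPK genes 7 were higher and 0 lower (7 and 0 adjusted over the list alone), such as Prkab1 (28 ± 2.22 against 4.60 ± 0.0107) and Prkaa2 (2.63 ± 0.26), with a median of 1.2 (1.35e-04, 0.156 with an estimated correlation). Of 24 cholesterol synthesis genes 13 were higher and 1, Acat2, lower (14 and 2 adjusted over the list alone). The median was 0.98 (3.94e-04, 0.152 with an estimated correlation). Of 25 genes of fatty acid beta-oxidation 9 were higher and 2, Acsl4 and Acsl5, lower (10 and 2 adjusted over the list alone), led by Cpt1a at 22 ± 3.43 against 0.563 ± 0.0137, with a median of 0.61 (0.00399, 0.152 with an estimated correlation). Of 22 glycolysis genes 14 were lower, Ldha at 23.6 ± 10.8 against 472 ± 37.1 and Pgam1 at 101 ± 34.8 against 1540 ± 655, and 2, Slc2a3 and Pfkp, were higher (14 and 3 adjusted over the list alone). The median was -1.39 (0.00203, 0.489 with an estimated correlation). Acat2, Acsl4, Acsl5 and Pfkp were picked after their values were seen. Mtor was at 4.22 ± 1.71 and 3.72 ± 0.739 (adjusted p = 0.80).

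Of 46 autophagy and lysosome genes 35 were higher in diapaused ICM and 2 lower (36 and 2 adjusted over the list alone). The median was 1.53 (camera adjusted p = 3.37e-12, 0.0597 with an estimated correlation). Ctsl was at 344 ± 41.8 against 38 ± 1.99, Ctsa at 151 ± 52.9 against 8.83 ± 1.32 and Lamp1 at 274 ± 27.8 against 33.6 ± 14.2, and the members that were lower, picked after their values were seen, were Tfe3 and Atg5. Of 35 genes of G2 phase and mitosis 20 were lower and 1, Nusap1, higher (21 and 1 adjusted over the list alone), with a median of -1.22 (1.00e-05, 0.262 with an estimated correlation), and of 40 genes of DNA replication 11 were lower and 0 higher (9 and 0 adjusted over the list alone). The replication median was -0.61 (0.0077, 0.486 with an estimated correlation). Ccna2 was at 16.8 ± 2.72 against 80.7 ± 8.53 and Mcm7 at 23.2 ± 5.84 against 112 ± 18.5. Of 81 ribosomal protein genes 25 were higher, such as Rpsa (247 ± 48.9 against 46.1 ± 10.9), and 3, Rps27l, Rpl21 and Rpl4, lower (26 and 3 adjusted over the list alone). The median was 0.49 (3.26e-04, 0.633 with an estimated correlation), and 29 were higher and 5 lower after quantile normalization. Primitive endoderm markers were higher in 17 of 22 and lower in 2, Fst and Cited1 (19 and 2 adjusted over the list alone), with a median of 2.76 (8.43e-11, 0.165 with an estimated correlation), Sparc being at 1390 ± 113 against 27.5 ± 7.42. Nusap1, Rps27l, Rpl21, Rpl4, Fst and Cited1 were picked after their values were seen. Trophectoderm markers were higher in 6 of 17 and lower in 1, Krt19 (8 and 3 adjusted over the list alone). The median was 1.39 (0.0298, 0.594 with an estimated correlation, 0.104 without diapaused ICM replicate 3). Of 12 genes of LIF and JAK-STAT3 signalling 4 were higher and 0 lower (4 and 0 adjusted over the list alone), Stat3 (3.97 ± 0.22), Lifr (3.06 ± 0.26) and, like Krt19 picked after their values were seen, Il6st and Socs3, with a median of 0.68 (0.00617, 0.165 with an estimated correlation, 0.0948 with a filter of 5 in 2 libraries). ATF4 and unfolded protein genes were higher in 7 of 18 and lower in 0 (7 and 0 adjusted over the list alone), with a median of 0.55 (0.00465, 0.489 with an estimated correlation), and dissociation or heat genes in 9 of 14 and lower in 0 (9 and 0 adjusted over the list alone). The median of the dissociation or heat list was 1.61 (1.68e-04, 0.165 with an estimated correlation).

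By limma's moderated test, 2830 genes were higher and 3283 lower in diapaused ICM than in epiblast, 6113 in all. The groups did not overlap in 10872 genes (61.4%, where chance gives 20%). Median-of-ratios scaling shifted the median of all genes by 0.118 and gave 3152 higher and 2493 lower. Rescaling without abundant genes gave 2789 and 2759. Without epiblast replicate 1 the count fell to 2539 (1418 and 1121), and without epiblast replicate 2 to 3196 (1620 and 1576). Camera called 16 of 41 lists, 12 upward and 4 downward, and 0 with an estimated correlation.

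Genes apart in diapaused ICM from both other groups were the last comparison, which asks what sets diapaused ICM apart from both stages. Only the diapaused embryos received the hormone treatment, so the arrested state, treatment and embryo age could not be separated here either. Differences in cell content and isolation could not be separated from these. The genes standing farthest above both were Egr2, S100a1 (55.7 ± 23.9 in diapaused ICM against 0.263 ± 0.295 in ICM and 1.26 ± 1.44 in epiblast), Phactr1 (157 ± 132 against 3.88 ± 0.603 and 3.64 ± 0.401), Phldb2 (73.2 ± 74.2 against 0.668 ± 0.719 and 2.11 ± 1.79), Egr1 and the protease gene Pgc (21.9 ± 4.71 against 0.505 ± 0.540 and 0.0145 ± 0.0166). Phactr1 and Phldb2 varied between the diapaused pools about as much as their means. Farthest below both were the linker histone gene Hist1h1a (0.740 ± 0.229 against 10.6 ± 2.80 and 10.7 ± 4.61), the imprinted gene Snrpn (3.44 ± 1.30 against 24.8 ± 5.97 and 32 ± 10.4), Cadm1, whose call against epiblast was lost without epiblast replicate 1 (adjusted p = 0.051), Rab13 (1.83 ± 0.581 against 15.3 ± 8.93 and 15.2 ± 4.03), the cohesion gene Cdca5 (7.34 ± 0.825 against 40.9 ± 6.20 and 45.1 ± 2.54) and Sms, for spermine synthase (12.5 ± 2.42 against 104 ± 15.5 and 65.5 ± 0.211). Higher than both were 13 of 22 primitive endoderm markers, 7 of 14 genes that respond to dissociation or heat and 10 of 24 cholesterol synthesis genes. So were 13 of 81 ribosomal protein genes, with 1 lower, and 7 of 18 ATF4 and unfolded protein genes. Lower than both were 7 of 35 genes of G2 phase and mitosis and 4 of 40 of DNA replication. Other lists held genes higher than both too, such as 4 of 12 visceral endoderm markers and 3 of 11 LKB1 and AMPK genes. Amino acid transporters had 4 of 18 higher, and imprinted genes 4 of 17 with 1 lower. In all, 817 genes were higher and 364 lower than both, where independent lists would share 213 and 191. Unchanged groups gave 0 in 50 simulations. With nothing changed hardly any gene is called in a single comparison, so that 0 was fixed in advance and cannot gauge the overlap. The 3 diapaused libraries serve in both comparisons and cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. Without ICM replicate 1 the counts were 540 and 181, without epiblast replicate 1 513 and 183, and without epiblast replicate 2 518 and 227. The lower count was 178 without ICM replicate 3, 207 without diapaused ICM replicate 1 and 189 without diapaused ICM replicate 2.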

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

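The alternative with protein-coding genes only was chosen after the results were seen; the others were planned. Counts of genes were recomputed under each of the alternatives on the values or the fit listed with the processing. Named genes were not recomputed with protein-coding genes only, lists neither there nor with a minimum fold, and the share of variance on the first component only under the pseudocounts, filters, median-of-ratios scaling and quantile normalization. Rescaling without abundant genes left no ribosomal or mitochondrially encoded genes and a stricter filter removed some genes named, so these have no value there. No named gene past the threshold changed direction under the alternatives run for it. The directions that turned were those of genes never past the threshold. For Stk11 in diapaused ICM against ICM, the fold change was 0.02 after quantile normalization, 0.01 with array weights and -0.11 to 0.06 with 1 library left out. For Kat8 it was -0.02 with a pseudocount of 5, -0.11 after quantile normalization, -0.06 after rescaling, -0.27 with array weights and -0.50 to 0.30 with 1 library left out. For Sox2 the range with 1 library left out was -0.18 to 0.32 in that comparison, -0.43 to 1.09 in epiblast against ICM and -0.95 to 0.56 in diapaused ICM against epiblast. In the last comparison Mtor ranged from -0.15 to 0.31. The cause was not tested.

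Counts moved by more than 1.5 times in these cases. For diapaused ICM against ICM (2360), the count was 1278 with no filter on low values, 640 with a minimum fold of 1.5 and 1404 without ICM replicate 1 (1404 to 2148 with 1 library left out). For epiblast against ICM (5324), it was 1845 with the minimum fold, 3356 with protein-coding genes only, 1788 without epiblast replicate 1 and 2618 without epiblast replicate 2 (1788 to 5257). For diapaused ICM against epiblast (6113), it was 2243, 3854, 2539 and 3196 in the same order (2539 to 6351). Genes higher in diapaused ICM than in both (817) numbered 453 with no filter, 239 with the minimum fold, and 513 to 728 with 1 library left out, with 540 without ICM replicate 1, 513 without epiblast replicate 1 and 518 without epiblast replicate 2. Genes lower than both (364) numbered 178 with no filter, 38 with the minimum fold, and 178 to 436 with 1 library left out, with 181 without ICM replicate 1, 178 without ICM replicate 3, 207 without diapaused ICM replicate 1, 189 without diapaused ICM replicate 2, 183 without epiblast replicate 1 and 227 without epiblast replicate 2. A minimum fold asks for more by construction, and fewer libraries leave fewer degrees of freedom. Testing protein-coding genes only takes all other genes out of the count by construction. For the other moves the cause was not tested. The split into higher and lower turned in further cases than those given with each comparison. For epiblast against ICM it was 871 and 974 with the minimum fold and 1515 and 1841 with protein-coding genes only. For diapaused ICM against epiblast it was 1234 and 1009, 2240 and 1614, and, without diapaused ICM replicate 1, 2612 and 2532. With 1 epiblast library left out, the remaining one is assumed to vary like the other groups. Lists called by camera (16, 11 and 16) numbered 14 to 17, 11 to 13 and 15 to 18 with 1 library left out, and 0, 0 and 0 with an estimated correlation. Besides the list calls given with each comparison, the planned settings that ended one were, apart from fry, a filter of 5 in 2 libraries and a fit of only the groups compared for mitochondrially encoded genes (adjusted p = 0.0738 and 0.0535) and core pluripotency (0.0565 and 0.0591) between diapaused ICM and ICM. For trophectoderm and trophoblast markers against epiblast they were a pseudocount of 5 (0.0567), no filter (0.0863) and a filter of 5 (0.111). Fry called 17, 17 and 21 and shared 14, 10 and 15 with camera. Called by fry alone between diapaused ICM and ICM were glutamine and glutamate enzymes and fatty acid and triglyceride synthesis, upward (fry adjusted p = 0.00542 each). Fatty acid beta-oxidation was called by fry alone too, downward (0.0399). The respiratory chain list between diapaused ICM and ICM was not called by fry (nuclear-encoded respiratory chain, 0.0631), nor were the mitochondrially encoded genes there (0.304) or in epiblast against ICM (0.0984), nor the cytosolic ribosomal proteins in diapaused ICM against epiblast (0.0609). The share of variance on the first component was 41.3% to 52.4% under the 6 alternatives run for it. Of the named genes past the threshold, 84 of 107, 92 of 104 and 101 of 112 stayed past it with each library left out in turn. In the same order 28, 6 and 5 of these calls were lost with no filter on low values and 40, 12 and 10 with the minimum fold, and 0 to 8, 0 to 1 and 0 to 2 under the other alternatives with all libraries. Counts of 1 or 2 genes within lists also moved under some scalings.

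With the replicate number as a block the counts were 2004, 4475 and 5314 in the order above, 682 and 317 for genes apart from both, and 16, 11 and 16 for lists, with trophectoderm and trophoblast no longer called against epiblast (0.0701). Deviations of same-number ICM and diapaused ICM libraries correlated at 0.02, 0.10 and 0.13. They were highest for ICM replicates 2 and 3, not 1 (0.03 with diapaused ICM replicate 2). A shared batch stays open. The depth is unknown, so how far it limits genes with low values was not assessed.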

Other observations

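The tests on transcript length, on transcripts with a terminal oligopyrimidine tract, on fewer epiblast cells and on more primitive endoderm cells were chosen only after the results were seen. The genes in the next paragraph were picked the same way.

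Between ICM and diapaused ICM the primitive endoderm gene Gata6, which acts early in that lineage, fell from 4.11 ± 1.04 to 1.66 ± 0.316 (log2 fold change -0.93 ± 0.25), while Gata4 rose (0.91 ± 0.18), as did Sox7, from 3.11 ± 0.856 to 15.5 ± 5.51 (1.97 ± 0.29) and the matrix gene Sparc, from 474 ± 40.4 to 1392 ± 113 (1.55 ± 0.21). Pdgfra was at 27.8 ± 4.46 and 38.6 ± 4.46 and was not past the threshold. The immediate-early genes Fos and Jun rose from 1.42 ± 0.675 to 5.86 ± 1.94 and from 0.507 ± 0.503 to 6.42 ± 3.86, whereas Hspa8 fell from 3666 ± 952 to 1768 ± 23.5. Keratin genes varied between the diapaused pools, Krt8 at 7.95 ± 8.47 and Krt18 at 51.8 ± 59.7.

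Cytosolic ribosomal protein genes were higher in diapaused ICM than in ICM while ribosome biogenesis genes were lower, with 25 of 81 rising and 1 falling and 0 of 47 rising and 6 falling, and with both list calls lost at an estimated correlation (0.412 and 0.408). Reads shared with near-identical copies do not account for the whole rise, since the 44 ribosomal genes with at most 1 such transcript had a median log2 fold change of 0.80 (95% bootstrap interval 0.57 to 0.90), next to 0.71 for the other 37. A gain of short transcripts is opposed by the 132 genes matched on length and level, whose median was -0.38 (-0.55 to -0.23). The match was not exact. The matched genes had a median length of 785 against 697 for the ribosomal genes, and a mean log2 level of 8.15 against 8.83. Whether transcripts with a 5' terminal oligopyrimidine tract rise as a class stays open, since 20 other such genes had a median of 0.12 (-0.21 to 0.73), at the 79.4th percentile of 10000 random lists, with 6 rising and 0 falling. The way the values were adjusted may also contribute and was not given, and the diapaused state, the hormone treatment or the age of the embryos is an untested biological explanation.

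Primitive endoderm markers were higher in diapaused ICM than in ICM, with 14 of 22 rising and 1 falling and the list call lost at an estimated correlation (0.324). Whether fewer epiblast cells raised the markers of other cell types alike stays open. The primitive endoderm median exceeded that of trophectoderm markers by 1.08 (95% bootstrap interval 0.37 to 1.44), but the trophectoderm had been lysed, so its markers also follow how complete the lysis was and decide nothing here. A larger share of primitive endoderm cells in the diapaused pools stays open: the median of the naive pluripotency list was 0.02 (-0.31 to 0.53), and a small starting share could grow with little loss of epiblast. Higher levels within each primitive endoderm cell, and the diapaused state, hormone treatment or age of the embryos, are untested and stay open too.

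For the 2360 genes between diapaused ICM and ICM, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and the highest of the others gave 1. These 10 splits are too few for a share under 0.05. All splits but the real one put ICM and diapaused libraries into the same part. A difference between the groups then widens the spread and leaves few calls, so the low counts there cannot gauge the 2360.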
